A study of Mus musculus with 16 samples.

How the data were processed

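RNA was sequenced from lung endothelial cells of female C57BL/6N mice, purified by fluorescence-activated cell sorting. Per the labels, Lewis lung carcinoma cells, a mouse lung tumour line of the same strain background, were implanted under the skin. Cells were taken from mice without a tumour (d0), with a primary tumour (d15), after the tumour had been resected (d22) and with metastases (d36). Each time point had 4 libraries, which the series design calls independent biological replicates, so 16 libraries were used. Replicates were numbered as in the titles: 1, 2, 3 and 4 at d0, 3, 4, 5 and 6 at d15, 1, 4, 5 and 6 at d22 and 1, 7, 8 and 9 at d36. The title of d36 replicate 1 and the header of its RPKM column name day 29, and its time point field, which was followed here, reads d36. The labels do not settle which of them holds. The antibodies and gate of the sort, and the hour of collection, were not given in the sources used here. Per the labels, RNA was extracted with a PicoPure kit and libraries were made from 10 ng of total RNA with the SMARTer Ultra Low kit.

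The authors deposited one table of 17715 entries with an RPKM value (reads per kilobase of transcript per megaread) for each library, per the file headers. The same deposited table holds a log2 fold change and an adjusted p-value for d15, d22 and d36, per the file headers, with no comparison group named. STAR, DESeq2 and the mouse genome build mm10 stand in the submitters' processing notes without versions or roles. The gene annotation, the length used for RPKM and any filter were not given in the sources used here. Of the entries, 3443 carry an AK identifier, 1461 carry an Ensembl transcript identifier and 17 have symbols that a spreadsheet had turned into dates. Entries of these kinds were tested, and they are given in the text only as numbers of transcripts, except where a value has to be printed.

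Depth was estimated from the deposited RPKM values. Low values of a gene are whole multiples of the value of 1 read, and the size of that step gives the relative depth of the libraries, which ran from 0.836 to 1.361. With these depths, 464 of 4296 low entries (mean RPKM under 1) came out as whole reads in all 16 libraries, within a tolerance of 0.1 read and up to 40 reads, against 0 with wrong depths. From 70 genes with a single annotated transcript the depth was approximately 93.4 to 152.1 M (mega) reads, a ratio of 1.63 between the deepest and the shallowest library. At the lowest depth, an RPKM of 1 corresponds to approximately 93 reads per kilobase. Most entries did not come out whole in every library, so reads were not recovered and no count test was run.

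Values were analysed as log2(RPKM + 1), so fold changes of genes near or under 1 RPKM are understated. The 14303 entries with at least 1 RPKM in at least 4 of the 16 libraries were tested. One limma fit with an intensity trend covered the 4 groups, which share one estimate of the spread per gene, with no covariate. Libraries differed more from each other at d36 (r across genes down to 0.92) than at d0, d15 or d22 (0.98, 0.979 and 0.978). For genes that spread more at d36, the shared estimate is too small for contrasts with d36 and too large for the others. The 6 contrasts between time points were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method within a contrast at a threshold of 0.05. A moderated F test covered the 3 contrasts with d0. Values are given as mean RPKM ± SD of 4 libraries, and log2 fold changes with the standard error of limma.

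Gene lists were fixed from general knowledge before the data were examined: 35 lists of endothelial subtypes, signalling, growth, metabolism, RNA quality and other cell types. The 27 lists with at least 5 tested genes were tested in the 6 comparisons with camera, at a preset correlation between genes of 0.01, and p-values were adjusted over the 162 tests. Camera was also run with an estimated correlation. It made 77 calls with the preset and 0 with the estimated correlation, so every list result is given with both p-values. Without a test stayed the lists with fewer tested members: neutrophil (2 of 16 genes), T and NK cell (1 of 15), B cell (3 of 12), platelet and megakaryocyte (3 of 11), erythroid (3 of 12) and mesothelium (0 of 6). None of the 13 mitochondrially encoded genes was found under its mt- symbol and none of the 4 Y-linked genes was found, so these lists were not analysed here. A further 4 lists (circadian clock, glucocorticoid response, RNA processing, carcinoma cell) were written after the data had been seen and were adjusted separately.

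Named genes followed a rule fixed before the data were examined. Lrg1 is given in every comparison. The 10 largest rises and 10 largest falls on the log2(RPKM + 1) scale are given against d0, and 5 of each in the other comparisons, among genes that passed, with a mean of at least 2 RPKM in either group and no overlap between the libraries of the groups. Up to 4 members with the smallest p are given for a list, and 5 genes each way among those called in all 3 comparisons with d0. Some of the genes that the rule picks are not reported here. Positions come from GENCODE M21 on the same build. Transcript lengths and GC contents, matched by symbol for 11255 entries, by transcript identifier for 1275 and by older symbol for 602, were available for 10916 tested genes.

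The alternatives were another pseudocount (0.1), no filter, a stricter filter (5 RPKM), median-of-ratios scaling, quantile normalization, limma without trend, array weights, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Alternatives added after the data had been seen were the genes with an annotated length, removal of the length and GC trend, and a fit without the d36 libraries. The tests were run on simulated data first. With 200 changed genes among 14303, limma recovered 92.5% of log2 changes of 1 and 26.9% of log2 changes of 0.5 in the d15 against d0 layout, with 11 false calls. The corresponding shares were 95.5% and 23.9% for d22 against d0, with 10 false calls, and 92.5% and 31.3% for d36 against d0, with 7 false calls. For d22 against d15 they were 97% and 35.8% with 8 false calls, for d36 against d22 94% and 22.4% with 4, and for d36 against d15 94% and 34.3% with 10. Removal of a simulated length and GC trend over 10916 genes in the d22 against d0 layout lowered false calls from 4314 to 9 and recovered 200 of 200 changed genes. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.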

Results

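Gene expression was measured by RNA sequencing in lung endothelial cells, the cells that line the blood vessels of the lung, of mice that carried a subcutaneous Lewis lung carcinoma. This tumour is known to spread to the lung. The series has 4 groups of 4 libraries: mice without a tumour (d0), with a primary tumour (d15), after its resection (d22) and with metastases (d36). Approximate depth ran from 95.3 to 112.7 M (mega) reads at d0, from 93.4 to 125.8 at d15, from 105.7 to 110.3 at d22 and from 103.2 to 152.1 at d36. The RPKM values of a library added up to 258126 to 331034. In each of the 16 libraries 12529 to 13834 of the 17715 entries had at least 1 RPKM, and 14303 entries were tested.

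Pan-endothelial genes were high in every library, with a list mean of 6.73 to 7.08 on the log2(RPKM + 1) scale. Libraries of a group were close to each other at d0 (r across genes 0.98 to 0.99), d15 (0.979 to 0.985) and d22 (0.978 to 0.989), and less so at d36 (0.92 to 0.984). Genes are not independent replicates, so these values carry no test. Principal component 1 held 39.9% of the variance and parted 3 of the d36 libraries, replicates 1, 7 and 8 at scores of 46.6, 57.5 and 42.9, from all others. Replicate 9 of d36 stood apart from its group with a score of -4.8. An F test over the contrasts with d0 called 4102 genes, and 2982 to 6294 when single libraries were left out, the highest without d36 replicate 9.

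**Figure D1:**
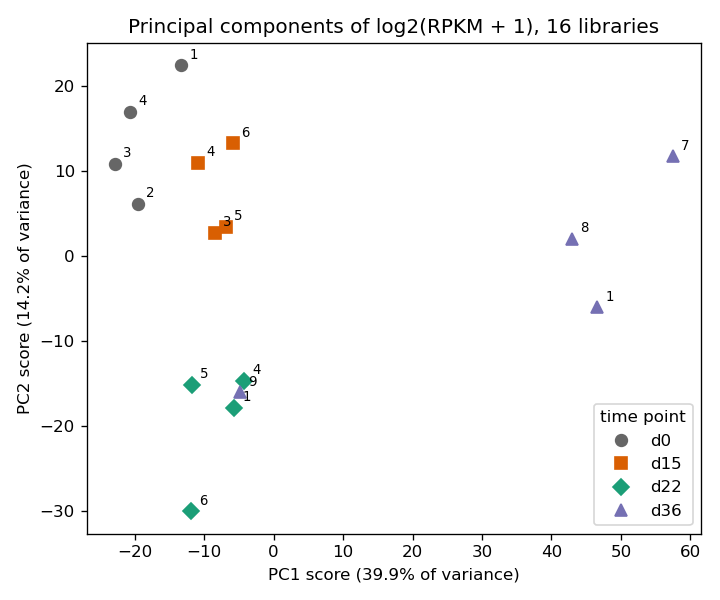
Principal components 1 (39.9% of the variance) and 2 (14.2%) of the 14303 tested entries on the log2(RPKM + 1) scale, 1 point per library, coloured by group, with the replicate number beside it. Replicates 1, 7 and 8 of d36 lie at 42.9 to 57.5 on component 1, and d36 replicate 9 lies at -4.8.

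The comparison of d15 with d0 asks how the endothelium of the lung differed while a primary tumour grew at another site. Lrg1, a secreted glycoprotein that modulates TGF-beta signalling in vessels, had the largest rise on the log2(RPKM + 1) scale: from 37.9 ± 9.87 to 308 ± 105 RPKM (SD, n = 4 each), a log2 fold change of 2.95 ± 0.48 (SE, adjusted p = 0.0106). The gene lies on chromosome 17 from 56119678 to 56122001 on the minus strand (mm10) and is annotated as protein coding. Venous genes and genes of the STAT3 and acute-phase response, to which Lrg1 belongs, were higher as groups, and genes of the aerocyte, the large alveolar capillary cell of gas exchange, were lower. None of these list calls held with an estimated correlation (adjusted p = 0.349 for each). In all, 87 genes rose and 82 fell, of which 24 and 20 changed at least 2-fold.

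Among the other rises at d15, Bhlhe40, a transcriptional repressor of the clock and of hypoxia, went from 9.15 ± 2.53 to 59.9 ± 27.8 RPKM (log2 fold change 2.51 ± 0.47, adjusted p = 0.0216). Clca1 as the table lists it, of a family that regulates chloride channels, rose by a log2 fold change of 2.31 ± 0.24 (adjusted p = 0.000222). Darc, the chemokine-binding receptor of venules, went from 0.182 ± 0.0576 to 3.29 ± 1.66 RPKM (1.78 ± 0.38, adjusted p = 0.0324). The haemoglobin gene Hba-a1 rose by 2.06, the clock-output factor Dbp by 1.69 and the heat shock gene Hspa1b by 1.66 (adjusted p = 0.0387, 0.0254 and 0.00302). The other 3 of the 10 largest rises were transcripts listed by identifier. Myl7, a myosin light chain of the heart atrium and the pulmonary vein wall, fell by 2.10 (adjusted p = 0.0458). Apln, which codes for the peptide apelin, fell from 20.8 ± 7.89 to 5.65 ± 1.45 RPKM (-1.67 ± 0.35, adjusted p = 0.0324). Next came Tekt5 (-1.36), Ms4a8a (-1.33), Enho, the gene of the peptide adropin (-1.30), the ferric reductase Frrs1 (-1.27) and the transmembrane glycoprotein Gpnmb (-1.24). The sulfotransferase Chst1 (-1.22), the matrix gene Egflam (-1.21) and the thromboxane receptor Tbxa2r (-1.21, adjusted p = 0.0116) completed the falls, all at adjusted p of at most 0.0458.

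Of 11 venous genes, 2 rose over all genes tested and 10 adjusted over the list alone: Vwf, the von Willebrand factor of endothelial storage granules (1.09, adjusted p = 0.0261), and the noradrenaline transporter Slc6a2 (1.58, adjusted p = 0.0458). The median of the list was 0.75 (adjusted p = 3.15e-09, and adjusted p = 0.349 with an estimated correlation). In the STAT3 and acute-phase list of 17 genes, Lrg1, the oncostatin M receptor gene Osmr (1.20, adjusted p = 0.0297) and the interleukin receptor gene Il4ra (0.88, adjusted p = 0.0461) rose, 3 in all, against 10 adjusted over the list alone. Its median was 0.79 (adjusted p = 4.04e-09, and adjusted p = 0.349 with an estimated correlation). Among 11 aerocyte genes Apln fell, 1 over all genes and 8 adjusted over the list alone, with a median of -0.81 (adjusted p = 2.32e-05, and adjusted p = 0.349 with an estimated correlation). NF-kB and leukocyte adhesion genes had 1 rise, Darc, among 19 and 5 adjusted over the list alone, with a median of 0.41 (adjusted p = 4.58e-05, and adjusted p = 0.432 with an estimated correlation). Of 5 lymphatic genes 1 rose, Fgl2 (1.11, adjusted p = 0.0261), and 4 adjusted over the list alone, with a median of 0.88 (adjusted p = 0.000531, and adjusted p = 0.165 with an estimated correlation).

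Markers of other cells moved as well at d15. The lung epithelium list of 15 genes, surfactant genes among them, had a median of 0.85 (adjusted p = 3.22e-05, and adjusted p = 0.349 with an estimated correlation). Its single call over all genes was a fall, of Hopx (-0.80, adjusted p = 0.0472), a gene of alveolar type I cells, and 7 members rose and 1 fell adjusted over the list alone. Of 6 cardiomyocyte genes 1 fell, Myl7, and 4 adjusted over the list alone, with a median of -0.69 (adjusted p = 0.00546, and adjusted p = 0.397 with an estimated correlation). The pan-leukocyte list mean was 1.55 ± 0.05 at d15 and 1.59 ± 0.19 at d0, and the list was not called. The erythroid list, with 3 tested genes and no test, had a mean of 0.73 ± 0.23 at d0 and 2.35 ± 0.71 at d15. Without d0 replicate 3 the cardiomyocyte median was -0.42.

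Smaller shifts were called at d15 in lists with few or no single calls. Of 18 Notch and angiocrine genes 1 rose, the endothelin gene Edn1 (0.63, adjusted p = 0.0332), and 5 rose and 1 fell adjusted over the list alone, with a list median of 0.17 (adjusted p = 0.00983, and adjusted p = 0.349 with an estimated correlation). Of 20 dissociation and immediate-early genes 1 rose, Hspa1b, and 4 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.00474, and adjusted p = 0.654 with an estimated correlation). No gene passed in limma over all genes in the lists that follow, which are given with their genes at an unadjusted p under 0.05. Arterial genes had a median of 0.36 with 0 calls adjusted over the list alone and 4 rises unadjusted (adjusted p = 0.00151, and adjusted p = 0.349 with an estimated correlation). Hypoxia genes had a median of 0.36 with 2 rises adjusted over the list alone and 4 unadjusted (adjusted p = 0.00177, and adjusted p = 0.428 with an estimated correlation). TGF-beta genes had a median of 0.24 with 1 rise and 1 fall adjusted over the list alone and 6 and 2 unadjusted (adjusted p = 0.0036, and adjusted p = 0.349 with an estimated correlation). General capillary genes had a median of 0.21 (adjusted p = 0.0155, and adjusted p = 0.349 with an estimated correlation), and ribosomal protein genes one of 0.10 (adjusted p = 0.0214, and adjusted p = 0.765 with an estimated correlation), with 0 calls adjusted over the list alone in either and 3 and 1 rises unadjusted. The calls of the general capillary list (length and GC trend removed), of the Notch and angiocrine list (without d0 replicate 1) and of the ribosomal list (without d15 replicate 3, passed in 5 of 8 such fits) were lost in the settings given here. Medians moved by over 1.5 times for arterial (0.22 without d0 replicate 1), Notch (0.31 without d15 replicate 5) and immediate-early genes (0.23 without d15 replicate 6) and for ribosomal genes (0.06 without d15 replicate 3 or 4, 0.19 without 5). The d15 counts rested on few libraries: 14 genes rose and 10 fell without d0 replicate 3, and 41 rose and 48 fell without d15 replicate 4. Where the text names a left-out library with an adjusted p, that is the highest of the 8 fits that each leave out a library. Of the 28 genes named for d15 against d0, 9 passed whichever library was left out, with Lrg1 at an adjusted p of at most 0.0462, Clca1, Hspa1b, Frrs1 and Tbxa2r among them. Myl7, Gpnmb and Egflam passed in 0 of the 8 fits, Darc, Hba-a1, Tekt5, Enho and Chst1 in 1, Apln in 2, Dbp in 3 and Bhlhe40 and Ms4a8a in 4.

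**Figure D2:**
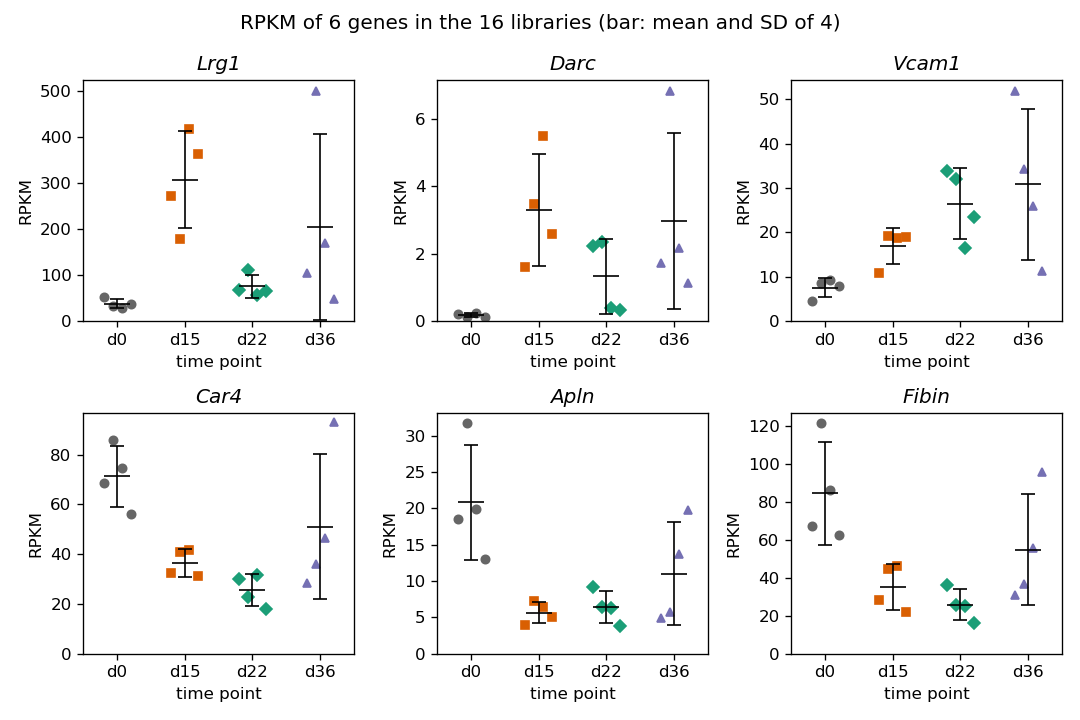
RPKM of Lrg1, Darc, Vcam1, Car4, Apln and Fibin in the 16 libraries (points) by time point, with the mean and SD of 4 libraries (bars). Lrg1 had a mean of 37.9 RPKM at d0, 308 at d15, 75.3 at d22 and 205 at d36, and Car4 had 71.3 at d0 and 25.6 at d22.

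The comparison of d22 with d0 asks what differed in the lung endothelium after the tumour had been removed. Vcam1, an adhesion molecule for leukocytes on activated and venous endothelium, rose from 7.58 ± 2.13 to 26.4 ± 8.02 RPKM (log2 fold change 1.67 ± 0.35, adjusted p = 0.00526). Car4, the membrane-bound carbonic anhydrase of aerocytes, fell from 71.3 ± 12.4 to 25.6 ± 6.42 RPKM (-1.46 ± 0.27, adjusted p = 0.00277). Venous genes were again higher and aerocyte genes lower, at adjusted p = 0.394 and 0.349 with an estimated correlation. Lrg1 stood at 75.3 ± 24.6 RPKM and did not differ from d0 at the threshold (0.95 ± 0.48, adjusted p = 0.193). Counts were larger than at d15: 1157 genes rose and 1016 fell, of which 65 and 35 changed at least 2-fold.

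The largest rise at d22 on the log2(RPKM + 1) scale was in Bpifa1, a secreted protein gene of the airway lining (2.28 ± 0.65, adjusted p = 0.0256), with 37.4 RPKM in d22 replicate 6 and 5.92 to 7.48 in the others. Without that library its change was 1.69 and did not pass (adjusted p = 0.0977, passed in 5 of 8 fits). ND4L, a mitochondrial gene of respiratory complex I, rose from 137 ± 46.6 to 452 ± 36.4 RPKM (1.77 ± 0.23, adjusted p = 0.000385). Slc6a2 (1.59, adjusted p = 0.00908), the heat shock gene Hspa1a (1.70) and Prrg1 (1.64) rose as well. Ssr3, of the complex that brings new proteins into the endoplasmic reticulum, rose from 9.07 ± 0.952 to 26.7 ± 0.535 RPKM (1.47 ± 0.10, adjusted p = 3.25e-07). Tmem45a (1.47), the matricellular gene Sparcl1 (1.44) and the transporter gene Atp13a3 (1.42) completed the 10. Nr1d1, a repressor of the circadian clock, fell from 35.1 ± 18.9 to 3.40 ± 0.602 RPKM (-2.86 ± 0.41, adjusted p = 0.000669). Cyp26b1, which breaks down retinoic acid (-2.02), Fibin (-1.68, adjusted p = 0.00363), Apln (-1.54), Chst1 (-1.52) and the growth-factor-binding gene Igfbp7 (-1.48) followed. Enho (-1.47), Car4, Tekt5 (-1.43) and the aminopeptidase Xpnpep2 (-1.43) completed the falls. The calls of Hspa1a (without d22 replicate 6, adjusted p = 0.07, passed in 4 of 8 fits), Cyp26b1 (without d0 replicate 4, adjusted p = 0.0546) and Xpnpep2 (without d0 replicate 1, adjusted p = 0.0718, passed in 5 of 8 fits) were lost when those libraries were left out.

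Of 11 venous genes 6 rose over all genes tested and 8 adjusted over the list alone. They included Nr2f2, the transcription factor that sets venous identity (1.05, adjusted p = 0.00296), and Bst1 (1.19, adjusted p = 0.00378), besides Vcam1 and Slc6a2. The list had a median of 0.91 (adjusted p = 6.39e-05, and adjusted p = 0.394 with an estimated correlation). Of 11 aerocyte genes 7 fell and 9 adjusted over the list alone, among them Car4, Fibin, Apln and the endothelin receptor gene Ednrb (87.5 ± 27.6 to 33.2 ± 10.5 RPKM, -1.37, adjusted p = 0.00708). Their median was -0.75 (adjusted p = 9.44e-05, and adjusted p = 0.349 with an estimated correlation). Oxidative phosphorylation genes coded in the nucleus had 5 falls among 20 and 6 adjusted over the list alone: Sdhb (-0.51), Ndufb8 (-0.57), Atp5o (-0.54) and Atp5g1 (-0.53) had the smallest p. The list median was -0.24 (adjusted p = 0.00237, and adjusted p = 0.475 with an estimated correlation). ND4L, which belongs to the same process and is coded in the mitochondrion, went the other way.

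Where a list is given with a single count from here on, its count adjusted over the list alone was equal. In the arterial list of 14 genes, the matrix genes Eln (0.83) and Ltbp4 (0.76) rose and the Notch ligand gene Dll4 fell (-0.38), with a median of 0.40 (adjusted p = 0.0232, and adjusted p = 0.422 with an estimated correlation). Of 6 cardiomyocyte genes 2 fell, Sln (-1.0) and Myl7 (-1.47), and 3 adjusted over the list alone, with a median of -0.52 (adjusted p = 0.0119, and adjusted p = 0.428 with an estimated correlation). Ribosomal protein genes had 2 falls among 27, Rpl18 (-0.48) among them, 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0346, and adjusted p = 0.771 with an estimated correlation). With the length and GC trend removed the ribosomal test pointed up (adjusted p = 0.877), and over its alternatives with the preset correlation the adjusted p ran from 0.00768 to 0.877. Cell cycle genes had a median of 0.38 with 0 calls in limma, also adjusted over the list alone, and 2 rises at an unadjusted p under 0.05 (adjusted p = 0.0462, and adjusted p = 0.807 with an estimated correlation). The pan-leukocyte list mean was 1.48 ± 0.12 at d22 and the list was not called. Single libraries ended 4 of these calls: arterial without d0 replicate 1 (adjusted p = 0.112), cardiomyocyte without d0 replicate 3 (adjusted p = 0.0632), ribosomal without d22 replicate 6 (adjusted p = 0.178, median -0.11, passed in 5 of 8 fits) and cell cycle without d22 replicate 1 (adjusted p = 0.365, median 0.22, passed in 4 of 8). Changes at d22 went with transcript length (Spearman rho 0.40 across 10916 genes, which are not independent) and GC content (-0.35), and with that trend removed 327 genes rose and 569 fell, against 865 and 957 of the same genes before.

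At d36 the mice had metastases, and tumour cells or leukocytes in the sort may be a source of rises against d0. Growth and inflammation genes were much higher: the monocyte chemokine Ccl2 went from 0.124 ± 0.188 to 129 ± 98 RPKM (log2 fold change 6.05 ± 0.79, adjusted p = 0.000106). Lgals1, the secreted lectin galectin, rose from 2.93 ± 0.541 to 362 ± 234 RPKM (5.94 ± 0.60, adjusted p = 1.39e-05). Cell cycle, hypoxia, NF-kB, STAT3 and pan-leukocyte genes were higher as groups. With an estimated correlation these lists had adjusted p = 0.36, 0.349, 0.397, 0.349 and 0.397. Lrg1 was again above d0 (205 ± 202 RPKM, 1.93 ± 0.48, adjusted p = 0.00845), with 104, 499, 170 and 48.8 RPKM in replicates 1, 7, 8 and 9. In all, 2376 genes rose and 1054 fell, of which 445 and 17 changed at least 2-fold. A fit of only d36 and d0, which has fewer libraries to estimate the spread, called 1524 rises and 528 falls.

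Cxcl1, a chemokine for neutrophils, had the largest rise on the log2(RPKM + 1) scale (6.07 ± 0.80), which understates changes of genes near 0 at d0. Rhox5, a homeobox gene silent in most adult somatic tissues and expressed in many tumour lines, rose from 0.103 ± 0.0804 to 87.0 ± 56.5 RPKM (5.85 ± 0.51, adjusted p = 4.44e-06). The growth regulator Myc (4.84), the calcium-binding genes S100a4 (4.78) and S100a6 (4.52), the chemokine Ccl7 (4.71), the metal-binding gene Mt1 (4.66) and the secreted factor Serpinf1 (4.54) rose as well, all with adjusted p of at most 0.000361. Replicate 9 of d36 was the lowest d36 library for several of these: Lgals1 had 539, 515, 363 and 31.1 RPKM and Rhox5 148, 97.8, 91.6 and 11.1 RPKM in replicates 1, 7, 8 and 9. Serpinf1 had 3.01 RPKM in replicate 9 and 50.2 to 54.1 in the others. Falls were smaller: the carboxylesterase Ces2e (-1.56, adjusted p = 0.0148), Tbxa2r (-1.26, adjusted p = 0.000456), the membrane metalloproteinase Mmp15 (-1.22, adjusted p = 0.00961) and Thrsp, a regulator of fat synthesis (-1.16, adjusted p = 0.0175). Without d36 replicate 7 the change of Ces2e was -0.96 and that of Mmp15 -0.81. The call of Thrsp was lost without d36 replicate 7 (adjusted p = 0.0591, passed in 6 of 8 fits). Cyp1a1, a target of the aryl hydrocarbon receptor, had -3.45 ± 1.05 (adjusted p = 0.0254), with 2050 RPKM in d0 replicate 1 and 54.7 to 100 in the other d0 libraries. Without d0 replicate 1 its change was -2.23 and did not pass (adjusted p = 0.0724, passed in 5 of 8 fits). The other 5 of the 10 largest falls were transcripts listed by identifier.

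Of 22 cell cycle genes 20 rose, and 20 adjusted over the list alone. Among them were the DNA-unwinding enzyme Top2a (0.116 ± 0.054 to 12.5 ± 7.23 RPKM, log2 fold change 3.35), the mitotic genes Ube2c (3.74) and Prc1 (3.04) and the kinase Cdk1 (3.64). The list had a median of 1.77 (adjusted p = 2.79e-12, and adjusted p = 0.36 with an estimated correlation). Its mean was 3.938, 3.36, 3.541 and 1.851 in d36 replicates 1, 7, 8 and 9, and 1.28 to 1.44 at d0. Ribosomal protein genes had 18 rises among 27 and 25 adjusted over the list alone, among them Rpl13 (1.38), Rpl4 (1.03), Rpl5 (0.67) and Rpl23 (1.33). Their median was 0.50 (adjusted p = 4.22e-07, and adjusted p = 0.4 with an estimated correlation). Of 14 hypoxia genes 11 rose and 12 adjusted over the list alone, among them the mitophagy gene Bnip3 (1.32), the vessel-dilating peptide Adm (3.02) and the glycolytic enzymes Ldha (31.0 ± 1.7 to 112 ± 54.4 RPKM, 1.65) and Pgk1 (1.06). The hypoxia list had a median of 1.1 (adjusted p = 2.35e-06, and adjusted p = 0.349 with an estimated correlation), with a mean of 4.02, 4.04, 3.94 and 2.89 in d36 replicates 1, 7, 8 and 9. Of 14 glycolysis genes, which share Ldha and Pgk1, 7 rose, also adjusted over the list alone, among them Pgam1 (0.96) and the glucose transporter Slc2a1 (1.64), with a median of 0.75 (adjusted p = 0.00129, and adjusted p = 0.475 with an estimated correlation).

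Of 19 NF-kB and leukocyte adhesion genes 12 rose at d36 and 14 adjusted over the list alone, with Cxcl2 (4.17), Ccl7, Ccl2 and Cxcl1 in front and a median of 1.17 (adjusted p = 1.07e-06, and adjusted p = 0.397 with an estimated correlation). Without d36 replicate 7 that median was 0.76. STAT3 and acute-phase genes had 12 rises among 17 and 14 adjusted over the list alone, among them serum amyloid gene Saa3 (2.66), the interleukin receptor Il1r1 (0.94) and Stat3 itself (0.76). The STAT3 median was 1.07 (adjusted p = 1.07e-06, and adjusted p = 0.349 with an estimated correlation). Immediate-early and dissociation genes had 11 rises among 20 and 14 adjusted over the list alone, such as Fos (2.46), Atf3 (2.67), Ier3 (1.72) and Hspa1b (1.76), with a median of 1.25 (adjusted p = 6.4e-05, and adjusted p = 0.475 with an estimated correlation). Beside these groups, leukocyte markers were higher: 6 of 8 pan-leukocyte genes rose, also adjusted over the list alone, with Itgb2, the leukocyte integrin chain (2.91), Cd52 (1.68), Tyrobp (2.45) and Rac2 (1.74). Their median was 1.91 (adjusted p = 0.000115, and adjusted p = 0.397 with an estimated correlation), and the list mean was 2.732, 3.769, 4.302 and 2.356 in d36 replicates 1, 7, 8 and 9. Of 8 monocyte and macrophage genes 5 rose, also adjusted over the list alone, among them Marco (2.23), Cd68 (1.80) and the complement gene C1qb (2.49), with a median of 1.62 (adjusted p = 0.00022, and adjusted p = 0.349 with an estimated correlation). Itgam, of the same list, was listed at 0 in the d0 libraries and had 1.99 ± 1.16 RPKM at d36.

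Of 26 type I interferon genes 4 fell, also adjusted over the list alone: Ifi35 (-0.76), Bst2 (-0.81), Irf7 (-0.78) and Isg15 (-0.76), with a median of -0.39 (adjusted p = 0.00123, and adjusted p = 0.657 with an estimated correlation). This median was -0.09 without d36 replicate 7 and -0.23 without d0 replicate 1. Pan-endothelial genes went both ways: 5 of 24 fell and 3 rose, and 6 fell and 3 rose adjusted over the list alone. The angiopoietin-pathway receptor Tie1 fell from 444 ± 26.6 to 276 ± 27.7 RPKM (-0.69) and the guidance receptor Robo4 by 0.70, and Ramp2 (1.21) and the transcription factor Fli1 (0.58) rose. The list had a median of -0.09 (adjusted p = 0.0482, and adjusted p = 0.349 with an estimated correlation), -0.05 without d0 replicate 4 and -0.14 without d36 replicate 7. Among aerocyte genes Prx (-0.84) and Apln (-0.99) fell and Nrp1 (0.54) rose, with a median of -0.51 (adjusted p = 0.0176, and adjusted p = 0.482 with an estimated correlation), and of -0.27 without d36 replicate 7. Of the venous genes 3 rose, Nr2f2 (1.04), Vcam1 (1.75) and the platelet-binding selectin Selp (1.54), with a median of 0.44 (adjusted p = 0.0438, and adjusted p = 0.654 with an estimated correlation).

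In the list for the change from endothelium to mesenchyme, 4 of 9 genes rose and 5 adjusted over the list alone, the matrix gene Fn1 (2.13), S100a4 and the transcription factors Snai1 (1.54) and Zeb2 (0.46) among them, with a median of 0.37 (adjusted p = 0.00669, and adjusted p = 0.349 with an estimated correlation). Of 23 TGF-beta genes 9 rose and 3 fell, and 11 rose and 3 fell adjusted over the list alone: Tgfbi (2.19), Smad2 (0.49) and Skil (0.91) rose and Id1 fell (-0.72), with a median of 0.38 (adjusted p = 0.0214, and adjusted p = 0.349 with an estimated correlation). Of 6 cardiomyocyte genes 2 fell, Myl7 (-1.82) and Sln (-1.15), with a median of -0.51 (adjusted p = 0.0104, and adjusted p = 0.428 with an estimated correlation), and of -0.33 without d0 replicate 3. The list calls lost without d36 replicate 7 were those of venous (adjusted p = 0.202, passed in 5 of 8 fits), type I interferon (0.138) and TGF-beta genes (0.0612), that of pan-endothelial genes was lost without d36 replicate 9 (0.09, passed in 4) and that of aerocyte genes without d0 replicate 2 (0.0703, passed in 6). The excess of rises over falls depended on the scaling: 1967 rose and 1640 fell with median-of-ratios scaling, 1713 and 1980 with quantile normalization, and 1055 and 1692 with the length and GC trend removed, against 2215 and 851 of the same genes before. Without d36 replicate 9, 3115 genes rose and 1898 fell. Without d36 replicate 1, which its title and column header place at day 29, 1848 rose and 703 fell. Whether that library was taken on another day was not tested.

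**Figure D3:**
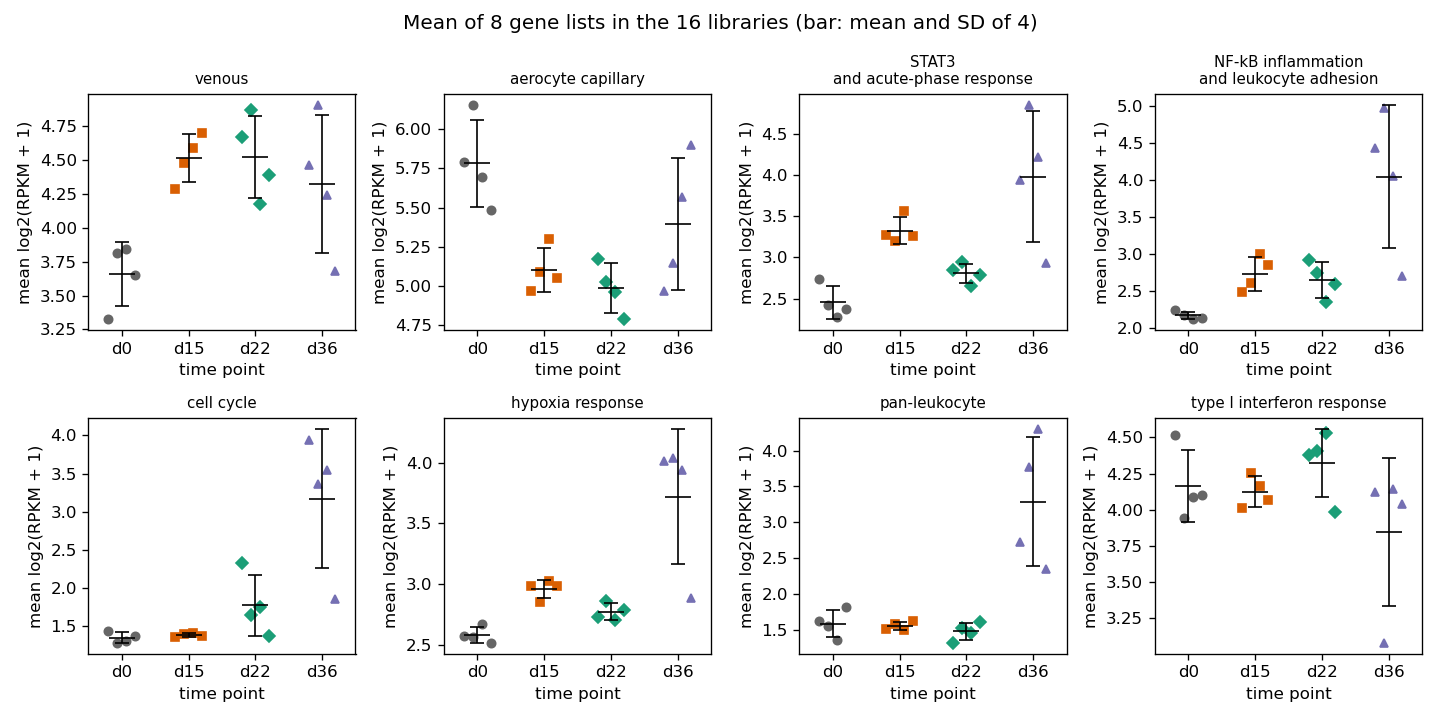
Mean log2(RPKM + 1) of 8 gene lists (venous, aerocyte capillary, STAT3 and acute-phase, NF-kB and adhesion, cell cycle, hypoxia, pan-leukocyte, type I interferon) in the 16 libraries (points) by time point, with the mean and SD of 4 libraries (bars). The venous mean was 3.66 at d0 and 4.52 at d22, and the cell cycle mean was 1.35 at d0 and 3.17 at d36, where d36 replicate 9 had 1.851.

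Between d15 and d22, around the resection, Nr1d1 had the largest fall, from 110 ± 46.1 to 3.40 ± 0.602 RPKM (log2 fold change -4.57 ± 0.41, adjusted p = 5.29e-05), its relative Nr1d2 fell by 2.19 (adjusted p = 0.000402) and Dbp by 1.91 (adjusted p = 0.00508). Arntl, the activator that Nr1d1 represses, rose from 3.75 ± 1.90 to 11.2 ± 1.47 RPKM (1.44 ± 0.24, adjusted p = 0.00429). Lrg1 fell from 308 to 75.3 RPKM (-1.99 ± 0.48, adjusted p = 0.0352). Its call was lost in 6 of 8 fits that left out a library, with the highest adjusted p, 0.102, without d15 replicate 6. In all, 286 genes rose and 151 fell, among the rises Prrg1 (1.42), the secreted matrix gene Spon2 (1.34), the NADPH oxidase Nox1 (1.27) and ND4L (1.27).

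The STAT3 and acute-phase list was lower at d22 than at d15: 2 of 17 genes fell, Lrg1 and Il4ra (-0.80), with a median of -0.52 (adjusted p = 0.000169, and adjusted p = 0.4 with an estimated correlation). Ribosomal protein genes had 1 fall among 27, Rps23 (-0.49), and 6 adjusted over the list alone, with a median of -0.29 (adjusted p = 2.25e-06, and adjusted p = 0.428 with an estimated correlation). Lung epithelium genes had 1 fall among 15, Napsa (-0.99), and 3 adjusted over the list alone, with a median of -0.45 (adjusted p = 8.67e-05, and adjusted p = 0.349 with an estimated correlation). Oxidative phosphorylation genes had 0 calls in limma, 3 falls at an unadjusted p under 0.05 and a median of -0.14 (adjusted p = 0.000531, and adjusted p = 0.428 with an estimated correlation). Monocyte and macrophage genes had 0 calls over all genes, 3 falls unadjusted and 2 falls adjusted over the list alone, with a median of -0.44 (adjusted p = 0.0183, and adjusted p = 0.475 with an estimated correlation). The glycolysis list had 1 fall, Pfkfb3 (-1.20), and a median of -0.13 (adjusted p = 0.029, and adjusted p = 0.668 with an estimated correlation). The dissociation and immediate-early list had 0 calls, also unadjusted, and a median of -0.25 (adjusted p = 0.0427, and adjusted p = 0.771 with an estimated correlation). Of these calls, glycolysis was lost without d22 replicate 6 (adjusted p = 0.0723, passed in 6 of 8 fits), and dissociation (0.259, passed in 4) and monocyte genes (0.0642) without d15 replicate 5. Medians moved by over 1.5 times for oxidative phosphorylation (-0.22 without d15 replicate 5), lung epithelium (-0.72 without d15 replicate 6) and glycolysis genes (-0.08 without d15 replicate 4, -0.07 without d22 replicate 6). The immediate-early median was -0.39, -0.12 and -0.16 without d15 replicate 4, d15 replicate 5 and d22 replicate 6. The rises outnumbered the falls here, and with median-of-ratios scaling they did not (230 and 278), nor with the length and GC trend removed (41 and 53, against 152 and 114 of the same genes before).

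Between d22 and d36, Rhox5 (5.52), Lgals1 (5.35), Ccl2 (5.18), S100a4 (4.54) and the lipid mediator enzyme Pla2g7 (4.32) had the largest rises on the log2(RPKM + 1) scale. Pla2g7 went from 0.421 ± 0.20 to 34.2 ± 19.5 RPKM. The histocompatibility gene H2-T24 (-1.01) and Nox1 (-0.98) fell, beside 3 transcripts listed by identifier. Lrg1 did not differ at the threshold (0.98 ± 0.48, adjusted p = 0.19). In all, 1249 genes rose and 439 fell, and 2291 and 1480 without d36 replicate 9. A fit of only d36 and d22, with fewer libraries for the spread, called 359 rises and 57 falls.

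Of 27 ribosomal protein genes 21 rose from d22 to d36 and 25 adjusted over the list alone, with a median of 0.74 (adjusted p = 2.15e-14, and adjusted p = 0.349 with an estimated correlation). Of 22 cell cycle genes 17 rose and 22 adjusted over the list alone, with Top2a at 2.51 and Plk1 at 2.06 and a median of 1.51 (adjusted p = 3.77e-12, and adjusted p = 0.36 with an estimated correlation). Glycolysis genes had 8 rises and 11 adjusted over the list alone, such as Tpi1 (1.32) and Eno1 (1.53), with a median of 0.85 (adjusted p = 2.25e-06, and adjusted p = 0.36 with an estimated correlation). Hypoxia genes had 9 rises and 11 adjusted over the list alone, with a median of 0.95 (adjusted p = 7.27e-06, and adjusted p = 0.349 with an estimated correlation). NF-kB genes had 6 rises and 7 adjusted over the list alone, with a median of 0.63 (adjusted p = 2.85e-05, and adjusted p = 0.428 with an estimated correlation). STAT3 genes had 6 rises, among them the protease inhibitor Timp1 (1.69), and 8 adjusted over the list alone, with a median of 0.79 (adjusted p = 1.34e-05, and adjusted p = 0.36 with an estimated correlation). Immediate-early genes had 9 rises, among them Egr1 (1.90), and 10 adjusted over the list alone, with a median of 0.94 (adjusted p = 1.19e-05, and adjusted p = 0.428 with an estimated correlation). Without d36 replicate 7 the medians of NF-kB, STAT3 and immediate-early genes were 0.29, 0.47 and 0.56. Leukocyte markers moved with them: pan-leukocyte genes had 6 rises among 8 and 7 adjusted over the list alone, with a median of 1.96 (adjusted p = 1.02e-06, and adjusted p = 0.349 with an estimated correlation). Monocyte and macrophage genes had 5 rises among 8, among them Cd68 (1.97), and 7 adjusted over the list alone, with a median of 1.70 (adjusted p = 2.52e-06, and adjusted p = 0.349 with an estimated correlation).

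Other lists shifted less from d22 to d36. The oxidative phosphorylation list had 2 rises, Atp5g1 (0.54) and Atp5a1 (0.42), and 7 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.000512, and adjusted p = 0.428 with an estimated correlation). Mesenchymal transition genes had 3 rises, Fn1 (2.01), S100a4 and Snai1 (1.66), and 4 adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0214, and adjusted p = 0.397 with an estimated correlation). Of 19 angiogenesis genes 3 rose, Adm (3.12), Unc5b (0.42) and the growth factor Pgf (1.29), with a median of 0.42 (adjusted p = 0.0482, and adjusted p = 0.394 with an estimated correlation). Type I interferon genes had 3 falls, Cmpk2 (-0.67), Irf7 (-0.69) and Dhx58 (-0.68), with a median of -0.47 (adjusted p = 3.69e-07, and adjusted p = 0.428 with an estimated correlation). General capillary genes had 1 fall, Ptprb (-0.38), and 4 adjusted over the list alone, with a median of -0.27 (adjusted p = 0.0121, and adjusted p = 0.349 with an estimated correlation). Pan-endothelial genes had 2 falls, Tie1 (-0.53) and Ptprb, with a median of -0.10 (adjusted p = 0.0145, and adjusted p = 0.349 with an estimated correlation). Arterial genes had 1 fall, Ltbp4 (-0.91), with a median of -0.33 (adjusted p = 0.0164, and adjusted p = 0.397 with an estimated correlation). The calls of angiogenesis (without d22 replicate 5, adjusted p = 0.115, passed in 4 of 8 fits), pan-endothelial (without d36 replicate 1, 0.056) and arterial genes (without d36 replicate 9, 0.0835) were lost without those libraries. Without d36 replicate 7 the medians of type I interferon, general capillary and angiogenesis genes were -0.19, -0.15 and 0.18, and without d36 replicate 9 those of angiogenesis and arterial genes were 0.27 and -0.16. The mesenchymal transition median was 0.09 without d22 replicate 1 and 0.26 without d22 replicate 5. With quantile normalization 929 genes rose and 899 fell.

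Between d15 and d36, the states with a primary tumour and with metastases, Lgals1 (5.94), Rhox5 (5.79), Ccl2 (5.68), Cxcl1 (5.39) and S100a4 (4.71) had the largest rises on the log2(RPKM + 1) scale. Zbtb16, a transcription factor induced by glucocorticoids, fell from 22.6 ± 4.15 to 5.32 ± 3.25 RPKM (-2.07 ± 0.32, adjusted p = 0.000912). The surfactant genes Sftpc (975 ± 572 to 291 ± 110 RPKM, -1.67) and Sftpa1 (-1.43) and the airway enzyme Cbr2 (-1.64) fell, with 1830 RPKM of Sftpc and 61.4 of Sftpa1 in d15 replicate 4 and 619 to 779 and 26.6 to 28.9 in the other d15 libraries. Cbr2 had 32.1 RPKM in d36 replicate 9 and 16.2 to 18.2 in the other d36 libraries. Lrg1 did not differ at the threshold (-1.01 ± 0.48, adjusted p = 0.19). In all, 1411 genes rose and 234 fell. A fit of only d36 and d15, with fewer libraries for the spread, called 366 rises and 35 falls.

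Of 22 cell cycle genes 20 rose from d15 to d36 and 21 adjusted over the list alone, among them Nusap1 (2.00), with a median of 1.89 (adjusted p = 6.26e-16, and adjusted p = 0.349 with an estimated correlation). Ribosomal protein genes had 5 rises and 17 adjusted over the list alone, with a median of 0.44 (adjusted p = 5.83e-06, and adjusted p = 0.428 with an estimated correlation). Hypoxia genes had 8 rises, among them P4ha1 (0.94), and 9 adjusted over the list alone, with a median of 0.66 (adjusted p = 0.000247, and adjusted p = 0.394 with an estimated correlation). The glycolysis list had 7 rises and a median of 0.64 (adjusted p = 0.0014, and adjusted p = 0.475 with an estimated correlation). The mesenchymal transition list had 4 rises and 6 adjusted over the list alone, with a median of 0.40 (adjusted p = 0.00485, and adjusted p = 0.349 with an estimated correlation). Immediate-early genes had 3 rises, Fos (1.83), Fosb (2.22) and Egr1 (1.54), and 5 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.00303, and adjusted p = 0.628 with an estimated correlation). The NF-kB list had 5 rises and a median of 0.41 (adjusted p = 0.0036, and adjusted p = 0.613 with an estimated correlation). Pan-leukocyte genes had 6 rises, also adjusted over the list alone, among them Fcer1g (2.25), with a median of 2.02 (adjusted p = 1.17e-05, and adjusted p = 0.349 with an estimated correlation). The monocyte and macrophage list had 5 rises, and 5 rises and 1 fall adjusted over the list alone, with a median of 1.45 (adjusted p = 0.0021, and adjusted p = 0.397 with an estimated correlation). Without d36 replicate 7 the medians of NF-kB and immediate-early genes were 0.21 and 0.33, and without d36 replicate 1 that of NF-kB genes was 0.25.

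Several lists of vessel genes were lower at d36 than at d15, and the aerocyte list was not called (median 0.34, adjusted p = 0.552). Pan-endothelial genes had 3 falls, Robo4 (-0.55), Tie1 (-0.48) and the junction gene Esam (-0.48), with a median of -0.20 (adjusted p = 9.15e-05, and adjusted p = 0.165 with an estimated correlation). General capillary genes had 2 falls, Gpihbp1, the anchor of lipoprotein lipase (-0.80), and Glp1r (-0.71), and 3 adjusted over the list alone, with a median of -0.37 (adjusted p = 0.000124, and adjusted p = 0.197 with an estimated correlation). The lymphatic list had 1 fall, the growth factor receptor Flt4 (-0.67), with a median of -0.40 (adjusted p = 0.0138, and adjusted p = 0.349 with an estimated correlation). The venous list had 1 fall, Ephb4 (-0.49), and 2 adjusted over the list alone, with a median of -0.30 (adjusted p = 0.0204, and adjusted p = 0.592 with an estimated correlation). The arterial list had 0 calls over all genes in limma, 2 falls at an unadjusted p under 0.05 and a median of -0.21 (adjusted p = 0.00646, and adjusted p = 0.36 with an estimated correlation). The type I interferon list had 0 calls over all genes, 3 falls unadjusted and a median of -0.32 (adjusted p = 0.000121, and adjusted p = 0.592 with an estimated correlation). The antigen presentation list of 23 genes had a rise of Cxcl10 (1.51) beside a median of -0.25 (adjusted p = 0.0155, and adjusted p = 0.765 with an estimated correlation), and its median without d36 replicate 7 was 0.08. Lung epithelium genes went both ways: the keratins Krt18 (3.18) and Krt8 (2.90) rose, 5 genes fell and 7 adjusted over the list alone, with a median of -0.45 (adjusted p = 0.00129, and adjusted p = 0.397 with an estimated correlation). Lost without d36 replicate 7 were the calls of type I interferon (adjusted p = 0.175), antigen presentation (0.387), NF-kB (0.148) and immediate-early genes (0.131), and lost without d36 replicate 9 those of venous (0.438, passed in 6 of 8 fits) and lymphatic genes (0.0665). Without d36 replicate 7 the medians of type I interferon, general capillary and venous genes were -0.01, -0.23 and -0.51, and without d36 replicate 9 those of venous and lymphatic genes were -0.12 and -0.25. The arterial median was -0.33 without d15 replicate 5 and the lung epithelium median -0.30 without d15 replicate 4. With median-of-ratios scaling 839 genes rose and 447 fell, with quantile normalization 783 and 574, and without d36 replicate 9 2306 and 669.

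Genes called in all 3 comparisons with d0 numbered 29 higher and 34 lower. Ssr3 rose by 0.51, 1.47 and 1.90 at d15, d22 and d36, Sparcl1 by 0.78, 1.44 and 2.06, Ythdf3, a reader of modified RNA, by 0.56, 1.02 and 1.09, and Clca1 by 2.31, 0.75 and 1.77. Fkbp11, a folding enzyme of the secretory pathway, fell by 0.90, 0.95 and 0.59, the zinc finger gene Zbtb48 by 0.69, 0.62 and 0.82 and Tbxa2r by 1.21, 1.05 and 1.26, beside 2 transcripts listed by identifier. In fits without 1 library, Sparcl1 at d15 and Clca1 at d22 passed in 0 of 8, Ssr3 at d15 in 4, Zbtb48 at d15 in 6 and Ythdf3 at d15 in 7. The 3 comparisons share the d0 libraries, which alone makes changes correlate: simulation without any effect gave r = 0.50 across genes, against 0.59 observed for d15 and d22, 0.52 for d15 and d36 and 0.51 for d22 and d36. The layout sets that simulated r, so near values do not show that the changes come from the shared libraries. Covariances were 0.0513, 0.0657 and 0.0784, against 0.0148, 0.0147 and 0.0147 simulated. With the d0 libraries split between the comparisons r was 0.27 to 0.52, 0.35 to 0.42 and 0.33 to 0.46. Shared calls were 37 higher and 61 lower for d15 and d22, 51 and 46 for d15 and d36, and 724 and 363 for d22 and d36. Independent sets of these sizes would share 7 and 5.8, 14.5 and 6, and 192.2 and 74.9. The simulation gave 0, which decides nothing, as it had no effect to call. With the d0 libraries so split the shared calls were 0 to 4 and 0 to 7, 2 to 6 and 0 to 2, and 214 to 330 and 39 to 84. Each comparison then had only 2 d0 libraries and called fewer genes, so these counts are not like those for independent sets. When single libraries were left out, 7 to 108 genes were higher and 4 to 95 lower in all 3 comparisons.

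The table that the authors deposited with the series lists 830 genes higher and 461 lower for d15, 2695 and 1504 for d22 and 2876 and 912 for d36 at an adjusted p under 0.05. Its fold changes correlated with those against d0 computed here at r = 0.952, 0.956 and 0.956 across genes, and 86 and 81, 1142 and 971, and 2128 and 775 genes were called in the same direction in both, with 0 in opposite directions. For Lrg1 the authors' table gives log2 fold changes of 2.95, 0.96 and 2.13. At d36 it gives no adjusted p for Cxcl1, Ccl2, Myc, S100a4, Ccl7 and Cyp1a1, beside log2 fold changes of 6.49, 5.33, 5.34, 6.88, 5.13 and -3.44. Its adjusted p at d36 is 0.235 for Ces2e. For Lgals1, Rhox5, Mt1, Serpinf1, S100a6, Tbxa2r, Mmp15 and Thrsp it is at most 0.0101. Of the 27 gene lists tested, those of basement membrane (smallest adjusted p = 0.801), unfolded protein response (0.0715) and fibroblast, pericyte and smooth muscle genes (0.0654) were called in no comparison. Median, mean and test had the same sign for each of the 77 list calls.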

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

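The tests of the 3 patterns weighed here were chosen only after the patterns had been seen, and the tests of single libraries and of directions were fixed earlier.

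Genes of growth, hypoxia and inflammation rose together at d36, and so did a carcinoma cell list of 20 genes written after the data had been seen, 3 of which the lung epithelium list holds: of 13 tested 10 rose and 0 lay below 0, with a median log2 change of 3.98 against d0 and levels of up to 362 RPKM (Lgals1) and 347 RPKM (S100a6). With an estimated correlation none of these lists passed in camera. Its adjusted p was 0.36 for cell cycle, 0.349 for hypoxia, 0.397 for NF-kB and 0.108 for carcinoma cell genes. For lung epithelial cells as the source, the lung epithelium list of 15 genes had a median of -0.45 (SE over members 0.39, 12 below 0) at d36 against d15 and of -0.11 (SE 0.38) against d0. The 12 members that the carcinoma list does not hold, a choice made after the full list had been seen, had a median of -1.12 (SE 0.2) against d15. Against d0 they had -0.15 (SE 0.12, 9 below 0). The values against d15 decide nothing, since d15 was high. More epithelial cells of the d0 kind would raise these genes, and the values against d0 showed no rise. They do not decide the question: the SE of the full list leaves room for a rise, and the 12 members were picked afterwards. The members Krt18 (3.98) and Krt8 (3.75) rose against d0. Epithelial cells as the source thus cannot be told apart from other cells. A mouse of another time point as the source of d36 replicate 9 cannot be told apart from a d36 mouse. For it, 272 genes were near 0 in the 12 libraries of d0, d15 and d22 (mean under 0.5 RPKM). They were present in d36 replicates 1, 7 and 8 (mean over the 3 of at least 2 RPKM). Of them 133, not most, were higher in d36 replicate 9 than in each of the 12. The count made for each of the 12, against the others and d36 replicate 9, was at most 67 (d22 replicate 1). Holding d36 replicate 9 among the libraries to exceed lowers that count, so 133 and 67 are not fully alike. Tumour cells or leukocytes carried through the sort (gate not given here) may be the source, and cannot be told apart from expression of these genes by endothelial cells of lungs with metastases, since 3.98 fits both and 10 of the 13 genes had at least 1 RPKM at d0.

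Clock genes differed among the groups: in a list written after the data had been seen, 9 of 12 tested genes were called by the F test over the contrasts with d0. A trend with gene length and GC content is argued against, since 8 of those 9 stayed called with the trend removed. The 4 group means of the list spanned 0.88 on the log2 scale, against at most 0.48 within a group. Time of day at collection is a candidate explanation that cannot be told apart from a change with tumour stage, because each time point is a single group and the hour is not given in the sources used here.

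Aerocyte genes were lower and venous genes higher at d22 against d0. Neither list call of camera held with an estimated correlation (adjusted p = 0.349 and 0.394). A length and GC trend is argued against for both lists: with the trend removed the aerocyte median was -0.73 (SE over members 0.21) and was -0.75 before, and 7 of 7 called members stayed called. The venous median was 0.88 (SE 0.13) and was 0.91 before, and 5 of 6 stayed called. A different mix of vessel segments in the sorted cells and a change of expression within the cells both stay open, untested, as does an effect of tumour and resection, which the design names.

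A library far from the others of its group was seen in 14 of 162 gene and group pairs, where chance gives 8.1, and in 6 of 108 list and group pairs, where chance gives 5.4. The value tested is the gap to the nearest library as a share of the range of the group. At d0 it was 0.977 for Cyp1a1 (replicate 1, 2050 RPKM), 0.885 for Ccl2 (replicate 1, 0.403 RPKM) and 1 for Ccl7 (replicate 4, 0.0599 RPKM, the others listed at 0). At d15 it was 0.934 for Sftpa1 and 0.868 for Sftpc (both replicate 4), 0.863 for Myl7 (replicate 4, 1.84 RPKM), 0.846 for Prrg1 (replicate 6, 1.09 RPKM, the lowest) and 0.934 for Sparcl1 (replicate 3, 6.2 RPKM). At d22 it was 0.95 for Bpifa1 (replicate 6), 0.895 for Ccl2 (replicate 1, 5.45 RPKM), 0.883 for Clca1 (replicate 4, 5.62 RPKM) and 0.841 for Dbp (replicate 1, 1.56 RPKM). At d36 it was 0.872 for Cbr2 and 0.924 for Serpinf1 (both replicate 9). Among list means it was 0.933 for arterial genes at d0 (replicate 1, the lowest) and 0.991 for glycolysis genes at d22 (replicate 6, the lowest). For type I interferon genes at d36 it was 0.902, where replicate 7 was the lowest at 3.08. Replicate 9 was the library far below the others at d36 for glycolysis (0.839), hypoxia (0.909) and unfolded protein response genes (0.864).

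Some genes passed against d0 in opposite directions at 2 time points. They were picked for that, so the difference between the time points, given here as a log2 value with adjusted p of at most 0.00153, is no separate evidence, and the number that chance gives was not computed. From d15 to d22, Nr1d2 differed by -2.19, Tspan4 by -1.45 and Ttpal by -0.82. From d15 to d36, Plau, a protease that activates plasminogen, differed by 1.66. From d22 to d36, Plau differed by 1.61, Nr1d2 by 1.77, Rpl23a by 0.94, Nme2 by 0.87, Cstb by 0.80 and Tmem55b by 0.68. The transcripts AK036409, AK146637 and ENSMUST00000060257 differed by -1.21, 0.82 and 0.76 between the same time points.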

How the results depend on the processing

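The tests with only genes of annotated length, with the length and GC trend removed and without the d36 libraries were chosen only after the data had been seen. Of 7241 values of 392 gene results under the alternatives, 6473 kept direction and side of the threshold, 547 no longer passed, 220 passed that had not and 1 reversed. Of 1371 values of 77 list results, 1197 kept both, 173 no longer passed and 1 reversed. The reversals were Ccl21a at d36 against d15 without d15 replicate 3 (0.04, and down to -0.58 without d36 replicate 7) and the ribosomal list at d22 against d0 with the length and GC trend removed, whose median was -0.06 and whose test pointed up (adjusted p = 0.877). With an estimated correlation 0 lists passed in camera, where 77 passed with the preset. Where no cause is named here, the cause was not tested.

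When each library was left out in turn, lowest and highest counts were as follows, with fewer libraries a part of the cause. Against d0, 14 to 41 rose and 10 to 48 fell at d15 (lowest without d0 replicate 3), 720 to 1030 and 446 to 761 at d22, and 1788 to 3115 and 638 to 1898 at d36 (highest without d36 replicate 9). For d22 against d15 they were 80 to 281 and 41 to 213, for d36 against d22 712 to 2291 and 160 to 1480, and for d36 against d15 798 to 2306 and 99 to 669. The F test called 2982 to 6294 genes and camera 71 to 81 lists. Shared calls of d15 and d22 were 8 to 30 higher and 7 to 53 lower, of d15 and d36 11 to 178 and 6 to 142, of d22 and d36 468 to 922 and 181 to 562, and of all 3 7 to 108 and 4 to 95.

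Other counts moved by over 1.5 times as follows, higher before lower. With array weights, which give less weight to libraries far from their group, there were 370 and 367 at d15 against d0, 2198 and 1747 at d22, 3602 and 2084 at d36, 852 and 429 for d22 against d15, 2553 and 1464 for d36 against d22, 2325 and 533 for d36 against d15 and 7530 by the F test. Shared calls were then 206 and 242 for d15 and d22, 265 and 245 for d15 and d36, 1345 and 795 for d22 and d36, and 177 and 160 for all 3. In fits of only the 2 groups compared there were 262 and 216 at d15 against d0, 1785 higher at d22, 1524 and 528 at d36, 541 and 251 for d22 against d15, 359 and 57 for d36 against d22, and 366 and 35 for d36 against d15. Shared calls were 138 and 137 for d15 and d22, 115 higher for d15 and d36 and 82 higher for all 3. Without the d36 libraries there were 342 and 310 at d15 against d0, 811 and 384 for d22 against d15, and 170 and 194 shared by d15 and d22. With the filter at 5 RPKM, which tests fewer genes, there were 602 higher at d22 and 1291 at d36 against d0, 126 higher for d22 against d15, 191 lower for d36 against d22, 782 higher for d36 against d15, 2628 by the F test and 443 higher shared by d22 and d36. With the length and GC trend removed, over the genes with an annotated length, there were 327 and 569 at d22, 1055 and 1692 at d36, 41 and 53 for d22 against d15, 640 higher for d36 against d22, 633 and 553 for d36 against d15, and 21, 186 and 18 higher shared by d15 and d22, by d22 and d36 and by all 3. Before removal the same genes gave 865 and 957 at d22, 2215 and 851 at d36, 152 and 114 for d22 against d15, 1155 higher for d36 against d22, and 1427 and 213 for d36 against d15. Genes with an annotated length alone gave 152 higher for d22 against d15 and 160 lower for d36 against d22. Median-of-ratios scaling gave 1640 lower at d36, 278 lower for d22 against d15, 839 and 447 for d36 against d15, 608 lower shared by d22 and d36 and 44 higher in all 3. Quantile normalization gave 1980 lower at d36, 899 lower for d36 against d22, and 783 and 574 for d36 against d15. With no filter 22 were higher at both d15 and d22, and with the pseudocount of 0.1 46 were higher in all 3. List calls ended by settings other than a left-out library included the following. Quantile normalization ended those of general capillary genes at d15, cell cycle, ribosomal and oxidative phosphorylation genes at d22, aerocyte and pan-endothelial genes at d36 against d0, oxidative phosphorylation, glycolysis and immediate-early genes at d22 against d15, oxidative phosphorylation and angiogenesis genes at d36 against d22, and venous and antigen presentation genes at d36 against d15. Removal of the length and GC trend ended those of general capillary genes at d15, of ribosomal genes at d22, of cardiomyocyte genes at d22 and d36 and aerocyte genes at d36 against d0, of glycolysis, monocyte and immediate-early genes at d22 against d15, of oxidative phosphorylation genes at d36 against d22, and of arterial, lymphatic, venous and antigen presentation genes at d36 against d15. Array weights ended those of type I interferon, TGF-beta and venous genes at d36 against d0, among others. Medians of all genes moved by over 0.1 with quantile normalization for d36 against d15 (from 0.062 to -0.041), and with the length and GC trend removed for d36 against d15 (to -0.055) and d36 against d0 (from 0.043 to -0.08), and by less in the other comparisons under each scaling.

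In limma fits of the 2 groups compared with the replicate number as a block, 18 genes rose and 0 fell at d15 against d0, 0 and 0 at d22, 127 were higher and 105 lower at d22 than at d15, and 0 and 0 were shared by d15 and d22. The F test, in a fit of all 16 libraries with the block, called 1789. In a block fit of 2 groups, only libraries whose number stands in both groups inform the contrast, and little is left to estimate the spread. The layout alone thus lowers the calls, so their fall says little about the changes themselves. An unadjusted p under 0.05 was reached by 2161 genes at d15 against d0, 3491 at d22 against d0 and 2642 at d22 against d15 with the block, and by 2873, 5260 and 3491 in the same fits of 2 groups without it. The values showed no clear pairing by number: in the 9 pairs of the same number, the correlation of group-centred values had a median of 0.04 (-0.11 to 0.22). In the 87 other pairs it was -0.02 (-0.36 to 0.35). No test was made of this, and a pairing is not excluded. The d36 comparisons share at most 1 number with another group and had no block fit of 2 groups. Genes at 1 RPKM had approximately 93 reads per kilobase in the shallowest library, and the log2(RPKM + 1) scale understates their changes. The 4 libraries of a group limit the changes that can be called: 23.9% of simulated log2 changes of 0.5 were recovered at d22 against d0.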

Other observations

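The gene lists of circadian clock, glucocorticoid response, RNA processing and carcinoma cells, and the tests on them, were chosen only after the data had been seen, and the tests of other splits were fixed earlier. The p-values of these lists are therefore no separate evidence that their genes changed. The carcinoma cell list, for example, holds Lgals1, S100a4 and S100a6, which were among the largest rises at d36.

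RNA-processing genes were higher at d22 than at d0. Of 20 genes for splicing factors and nuclear-retained RNAs 13 rose over all genes tested and 15 adjusted over the list alone, among them the RNA-binding genes Tia1 (0.95), Rbm39 (0.87) and Rbm25 (0.82) and the splicing factor Srsf11 (0.68). The list had a median of 0.61 (adjusted p = 1.34e-09, and adjusted p = 0.0995 with an estimated correlation). At d15 its median was 0.22 (adjusted p = 0.000239, and adjusted p = 0.251 with an estimated correlation) and at d36 0.44 (adjusted p = 0.000471, and adjusted p = 0.265 with an estimated correlation). Its mean was highest in d22 replicate 6 (4.36) and d36 replicate 9 (4.244), and changes at d22 went with transcript length (Spearman rho 0.40 across genes) and GC content (-0.35).

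Clock genes were higher at d15 than at d0: 4 of 12 rose over all genes, and 7 rose and 1 fell adjusted over the list alone, with a median of 0.89 (adjusted p = 3.52e-07, and adjusted p = 0.0143 with an estimated correlation). Since this list was written after clock genes had been seen to change, its p-values only describe that change. From d15 to d22, 1 clock gene rose and 5 fell, and 1 rose and 7 fell adjusted over the list alone, with a median of -0.85 (adjusted p = 0.00022, and adjusted p = 0.0636 with an estimated correlation). Genes induced by glucocorticoids had a median of 0.62 at d15 against d0 (adjusted p = 0.000102, and adjusted p = 0.0995 with an estimated correlation). The carcinoma cell list had 10 rises among 13 at d36 against d0, Lgals1, S100a6, S100a4 and Anxa1 (4.25) among them (adjusted p = 3.83e-09, and adjusted p = 0.108 with an estimated correlation). Its mean was 5.769, 5.482, 5.169 and 2.833 in d36 replicates 1, 7, 8 and 9, and 1.451 to 1.698 at d0. The B cell list, with 3 tested genes and no test, had a mean of 0.77 ± 0.30 at d0 and 2.54 ± 1.41 at d36. Among other lists without a test, the neutrophil mean was 1.22 ± 0.29 at d0 and 1.92 ± 0.85 at d36, that of T and NK cells 1.52 ± 0.11 and 1.39 ± 0.42 and that of platelets and megakaryocytes 1.07 ± 0.13 and 1.86 ± 0.36. At d15 and d22 the neutrophil mean was 1.48 ± 0.3 and 1.55 ± 0.26. That of T and NK cells was 1.26 ± 0.15 and 1.03 ± 0.06, and that of platelets and megakaryocytes 1.4 ± 0.12 and 1.3 ± 0.13.

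In each comparison below only 1 of the 35 splits of 8 libraries, the real split, called as many genes. This argues against a chance split as the source of each count. It does not exclude one, since 1 of 35 is the smallest share that the test can give. Nor can the splits tell the time point from anything else that the libraries of a group share. The real count was 169 and the highest other 23 for d15 against d0, 2173 and 0 for d22 against d0, and 437 and 1 for d22 against d15, where limma found 2353, 4265 and 2910 genes at an unadjusted p under 0.05 in the real split. For d36 the highest other splits exchanged d36 replicate 9 with a library of the other group: 2577 beside the real 3430 against d0, 1618 beside 1688 against d22 and 805 beside 1645 against d15, which points to the place of that library in its group. In 100 splits of the 16 libraries the F test called at most 11 genes in any but the real one, which called 4102.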
